A study of Homo sapiens with 4 samples.

How the data were processed

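Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on A549 cells, a lung adenocarcinoma line, that stably carried ATOH8 delivered by a retrovirus. There were 4 libraries: 1 ChIP with an antibody against FLAG, 1 ChIP with an antibody against SMAD3, and 1 input library, that is sonicated chromatin without antibody, for each ChIP. The FLAG ChIP is taken here as the reading of tagged ATOH8, as the series title and design imply. ATOH8 is a basic helix-loop-helix (bHLH) transcription factor, and SMAD3 carries signals of TGF-beta receptors to the nucleus.

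Reads were checked with FastQC 0.11.8, aligned with Bowtie2 and used to call peaks with MACS2 2.2.7.1 on hg38, per the submitters' processing notes, which give no Bowtie2 version. Each ChIP library was compared with its own input as single-end tags, with 1 tag kept per position and a p cutoff of 0.0065, per the file headers. Before that filter the FLAG ChIP held 20778990 tags and its input 23675838, and the SMAD3 ChIP held 20307213 and its input 19317284, per the file headers. After it, 17133946, 20785894, 16857119 and 17215727 tags were left in the same order. Fragment length was modelled as 241 bp in the FLAG ChIP and 203 bp in the SMAD3 ChIP, per the file headers.

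For each peak the authors deposited a start, an end, a summit, the pileup signal at the summit in tags, the fold enrichment of that pileup over the local background, and −log10 p and −log10 q values. The fold enrichment is a ratio of pileup plus 1 to background plus 1, so the background that the caller had used was computed from the 2 deposited columns and is called the implied input background here. Its lowest value equalled the genome-wide floor set by the ChIP depth, 1.53 tags in the FLAG list and 1.27 in the SMAD3 list. The headers state that q values would not be calculated, while the deposited −log10 q column holds values from 0 upwards, which were used as they stand. The p cutoff is permissive: a peak in either list is a region at or past that cutoff, and only part of the peaks has a q under 0.05. Fold enrichment was used to describe, rank or filter peaks within a list and was never tested across the lists.

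Gene positions came from a RefSeq gene table of GRCh38.p14 with 20037 protein-coding genes on assigned chromosomes, without strand, exons or sequence. The plan had been to count summits within 1 kb of a transcription start site. Because strand was not used here, a summit within 1 kb of either end of a protein-coding gene was counted instead, and such peaks are called gene-end peaks. Random gene lists were matched on decile of gene length in place of promoter GC content. Motif searches need the genome sequence and were not run, and exon, intron and UTR classes were not assigned.

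Overlap meant 1 bp or more, counted with code written in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Counts of overlapping peaks were equal to those from bedtools 2.31.1. Chance was described by 1000 random placements of the other list on the same chromosomes with widths kept. Positions without reference sequence could not be left out of the placements. Gene lists were described by 10000 random lists of the same size and the one-sided share of lists with as many members, with Benjamini-Hochberg adjustment over 20 lists within each peak list and window. Shared and unshared peaks were compared by a two-sided permutation test with 100000 permutations of the shared labels over peaks. Clopper-Pearson 95% intervals cover counting error only. With 1 ChIP library per antibody there are no replicates, so these values describe the libraries and test no difference between conditions.

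The code was tested on simulated data. Of 20 pairs of lists without planted sites 1 was called, and 217 overlaps were found where 200 had been planted on top of chance. Those lists were placed at random in the same way as in the test. They check the code, and not whether random placement suits peaks that cluster in the same regions. Of 200 simulated gene lists without planted peaks 2 were called, and all 200 with 5 planted members out of 60 were called. That excess was large, since 1.79% of protein-coding genes carried a FLAG gene-end peak, and smaller ones were not simulated.

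The results, the tests, the alternatives and the rule for named genes were set before the data were examined. Named genes are the 10 genes per list with the strongest gene-end peak, up to 10 genes with a gene-end peak shared by both lists, up to 4 members of each gene list with the strongest gene-end peaks, 19 genes of the ATOH8, SMAD3, TGF-beta and cell cycle programmes with any peak in the gene or within 10 kb, and the 3 strongest peaks of each list. Genes outside that rule are named as chosen afterwards, and values of some genes that the rule covers are not reported here. Alternatives covered the threshold, the definition of overlap, the placement of random peaks, the window around gene ends and the matching of gene lists. Figures were drawn with matplotlib 3.10.9.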

Results

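The series profiled where FLAG-tagged ATOH8 and SMAD3 lie on the genome of A549 lung adenocarcinoma cells that carry ATOH8 on a retrovirus. Its title raises the question of whether both proteins act together on a cell cycle programme. The measurements are 2 peak lists, each from 1 ChIP library of about equal depth (17133946 tags for FLAG and 16857119 for SMAD3 after filtering) against its own input. Positions are in hg38.

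The strongest FLAG peaks lay in or near HDX, CP and AMN1. The first covered the end of HDX with the higher coordinate, without regard to strand. HDX is a homeobox gene on chromosome X. The peak (84501296 to 84505673) had a fold enrichment of 52.4 over input and a pileup of 354 tags. The next lay inside CP, the gene of the copper-carrying plasma protein ceruloplasmin (chromosome 3, 149178685 to 149180630), at 37.4-fold, and the third strongest lay 20.3 kb outside AMN1 (chromosome 12, 31748717 to 31749827), at 31.3-fold. Of 9466 FLAG peaks, 42 reached a fold of 10 or more. Of these 42, 20 lay inside a protein-coding gene, 4 were gene-end peaks and 6 overlapped a SMAD3 peak. Among FLAG peaks of that strength, widths ran from 403 to 4941 bp with a median of 994.5 bp. The median FLAG peak was far weaker, at 3.16-fold and 8 tags, and 2434 peaks (25.7%, 95% interval 24.8 to 26.6%) had a q under 0.05.

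The 5 strongest SMAD3 peaks lay in IL33, which encodes a cytokine of the interleukin-1 family. The first 3 spanned positions 6250349 to 6250720, 6251013 to 6251380 and 6252757 to 6253078 of chromosome 9, with folds of 28.4, 27.9 and 17. Only 6 SMAD3 peaks reached a fold of 10 or more: 5 in IL33 and 1 in ALKBH5, the gene of an RNA demethylase, at 12.2-fold (chromosome 17, 18184253 to 18185018). All 6 overlapped a FLAG peak. Of 7184 SMAD3 peaks, 567 (7.89%, 7.28 to 8.54%) had a q under 0.05, and the median peak stood at 3.09-fold and 7 tags. Counts of peaks depend strongly on the threshold: with a −log10 q of 5 or more, 681 FLAG and 85 SMAD3 peaks were left.

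**Figure D1:**
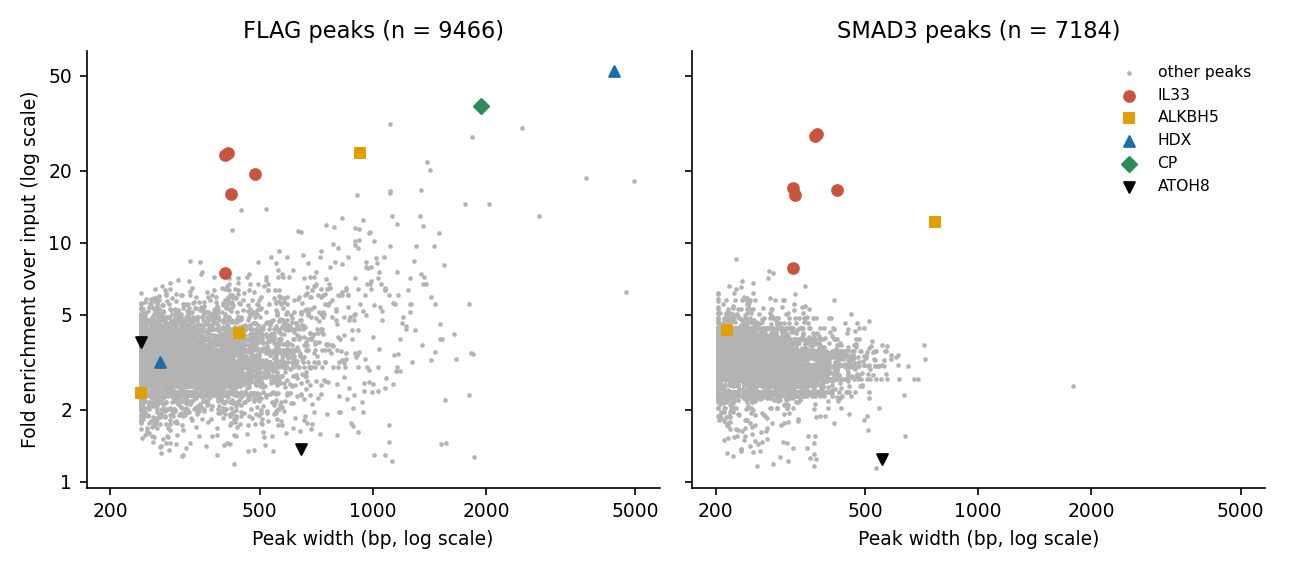
Width of each peak in bp (x axis, log scale) against the authors' fold enrichment over input (y axis, log scale) in the FLAG list (left, 9466 peaks) and the SMAD3 list (right, 7184 peaks), with peaks at 5 genes marked. HDX at 52.4-fold and CP at 37.4-fold are wide FLAG peaks. IL33 peaks in the FLAG list are narrower than these, at 403 to 487 bp, but wider than the list median of 276 bp. In the SMAD3 list the IL33 peaks reach 28.4-fold.

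Peaks were spread unevenly over chromosomes. Chromosome 20 held 7.21 FLAG and 6.03 SMAD3 peaks per Mb, while chromosome 4 held 1.15 and 0.515 and chromosome X 0.731 and 0.468. Both lists ranked the 23 chromosomes 1 to 22 and X alike, with a Spearman coefficient of 0.919 across chromosomes, which are not independent replicates.

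**Figure D2:**
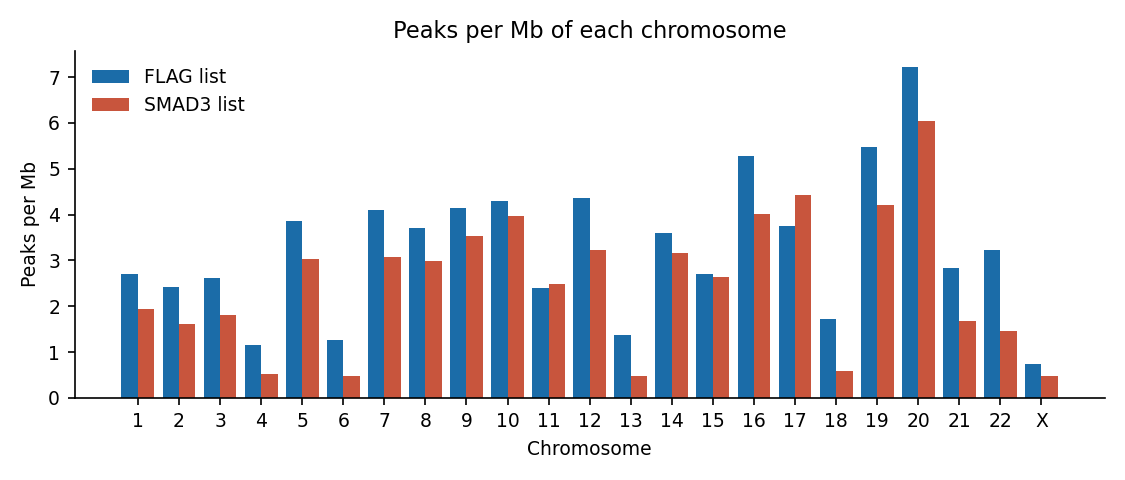
Number of peaks per Mb (y axis, from 0) on chromosomes 1 to 22 and X (x axis) in the FLAG list and the SMAD3 list. Chromosome 20 is highest in both lists, at 7.21 and 6.03 peaks per Mb, and chromosome X is lowest, at 0.731 and 0.468.

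Genes with the strongest gene-end peaks in the FLAG list were HDX, ALKBH5 (23.7-fold), ELOVL5, a fatty acid elongase (12.5-fold), TTYH2 (11.8-fold), PERP, a p53-induced membrane protein (8.37-fold), EIF5A2 (6.72-fold), EEF1A1, a translation elongation factor (6.35-fold), LOC124901868 (5.62-fold), PDLIM2 (5.47-fold) and XKR7 (5.22-fold). All 10 had a q under 0.05. In the SMAD3 list, ALKBH5 was followed by HBA2, an alpha-globin gene (5.41-fold), CLPS (4.85-fold), and GPR157, CYB5R1, P2RX1, C2CD2, ADSL, RUNX1T1 and VCX3A, each at 4.41-fold with 9 tags and a −log10 q of 1.34. Gene-end peaks made up 3.71% of FLAG peaks (338 of 9100 on assigned chromosomes, 95% interval 3.34 to 4.12%) and 3.97% of SMAD3 peaks (277 of 6979, 3.52 to 4.45%). Randomly placed lists gave 2.62% ± 0.165 (SD, n = 1000 placements) and 2.71% ± 0.194 (SD, n = 1000 placements), so the shares were 1.42 and 1.46 times chance, and no placement reached either. The excess was not seen among stronger peaks: at a −log10 q of 5 or more, 10 of 590 FLAG peaks (1.69%) lay at gene ends. That was 0.543 times chance, and 994 of 1000 placements gave as many. Of FLAG peaks with a q under 0.05, 47.6% lay over 250 kb from any gene, against 22.3% of all, so strength was not separated from distance. Without peaks far from genes, with high input background or at IL33, ALKBH5 and ATOH8 (chosen after seeing the data), shares were 1.74 (FLAG) and 1.37 (SMAD3) times those of peaks moved by 10 to 500 kb. All peaks gave 1.74 and 1.36 against moved peaks, so leaving those peaks out changed little. The lists left held peaks of every q, so strong peaks near genes were not examined apart. For FLAG the excess was also lost within 3 kb of a gene end, at 1.02 times chance.

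To compare both proteins, peaks were overlapped. Of 9100 FLAG peaks on assigned chromosomes, 217 (2.38%, 95% interval 2.08 to 2.72%) overlapped a SMAD3 peak, and 218 of 6979 SMAD3 peaks (3.12%, 2.73 to 3.56%) overlapped a FLAG peak. Random placement gave 14.9 ± 4.0 overlapping FLAG peaks (SD, n = 1000 placements), so the overlap was 14.6 times chance for FLAG and 15 times for SMAD3, and 0 of 1000 placements were as large. Against lists with each peak moved by 10 to 500 kb, a comparison chosen after seeing the data, the same peaks gave lower ratios of 6.05 for FLAG (35.9 ± 5.81 expected, SD, n = 1000 moved lists) and 6.18 for SMAD3, again with 0 of 1000 as large. Most shared peaks lay far from genes. Contigs included, 241 FLAG peaks were shared, of which 157 (65.1%) lay over 250 kb from any annotated gene, against 20.3% of unshared FLAG peaks. Shared peaks with a q under 0.05 in both lists formed 92 pairs: 62 lay over 250 kb from any gene, 13 on contigs and alternate sequences, 5 at IL33, 1 at ALKBH5 and 11 elsewhere. Of those 11, only 1 had a FLAG peak with an implied input background under 5 that lay outside ATOH8. In a comparison chosen after seeing the data, peaks over 250 kb from any gene, with an implied input background of 5 or more, or in IL33, ALKBH5 or ATOH8 were left out. Then 27 of 6851 FLAG peaks (0.394%, 0.260 to 0.573%) overlapped a SMAD3 peak, against 11.7 ± 3.31 (SD, n = 1000 moved lists) when each SMAD3 peak was moved by 10 to 500 kb. That is 2.31 times chance, to be set against 6.05 for all peaks, and 0 of 1000 moved lists were as large. With random placement the ratio was 2.81, against 14.6 for all peaks. Moved or placed peaks could land in the regions left out, so chance overlap may be understated and both reduced ratios too high.

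**Figure D3:**
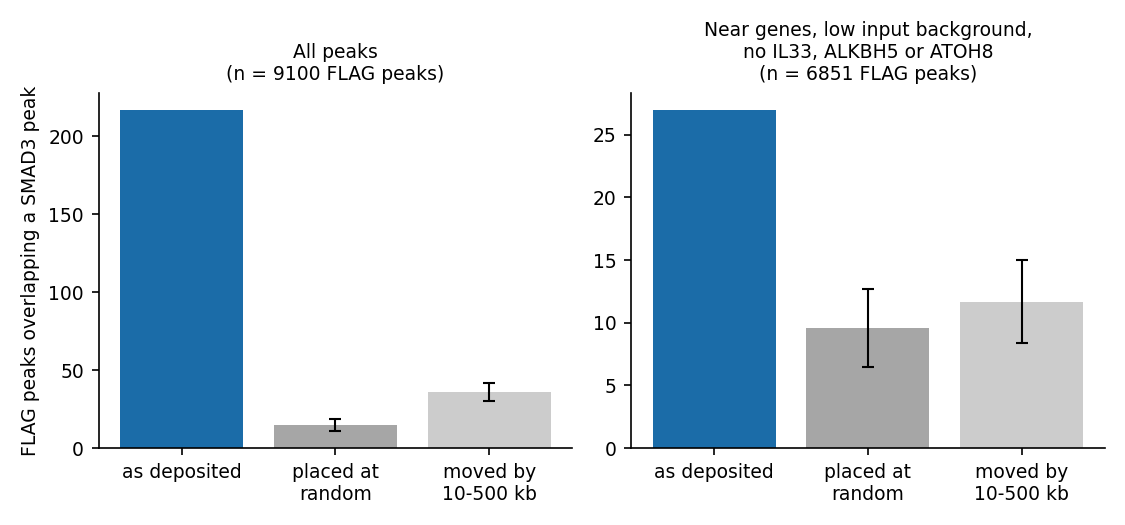
Number of FLAG peaks that overlap a SMAD3 peak (y axis, from 0) for the SMAD3 list as deposited, placed at random on the same chromosomes, or with each peak moved by 10 to 500 kb. Grey bars are means of 1000 placements with their SD. With all peaks 217 overlapped against 14.9 at random, and with the reduced lists on the right 27 overlapped against 11.7 in moved lists.

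At IL33 the FLAG list held 5 peaks and the SMAD3 list 6, and the 5 shared pairs had summits at most 16 bp apart. The FLAG peaks reached 23.6-fold (6250332 to 6250743) and had widths of 403 to 487 bp. At ALKBH5 and within 10 kb of it the FLAG list held 3 peaks and the SMAD3 list 2. The strongest FLAG peak spanned 18184141 to 18185065 and overlapped the strongest SMAD3 peak there. A weaker shared pair inside the gene (FLAG peak 18206795 to 18207035) had folds of 2.34 (FLAG, −log10 q of 0) and 4.32 (SMAD3, −log10 q of 2.77), with summits 31 bp apart. Gene-end peaks were shared at 4 genes: ALKBH5, EEF1A1 (6.35-fold in the FLAG list, 3.72-fold with a −log10 q of 0.708 in the SMAD3 list), PIAS1, a SUMO ligase (2.56-fold and 3.07-fold), and ATOH8. The PIAS1 peaks had a −log10 q of only 0.073 (FLAG) and 0 (SMAD3), with summits 220 bp apart. Summits at EEF1A1 lay 575 bp apart. At ATOH8 (chromosome 2, 85753991 to 85791383), the gene introduced by the retrovirus, pileups were 442 tags in the FLAG list and 371 in the SMAD3 list, on implied input backgrounds of 321 and 297 tags. The fold was 1.38 (−log10 q of 5.79) and 1.25 (−log10 q of 0.582).

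**Figure D4:**
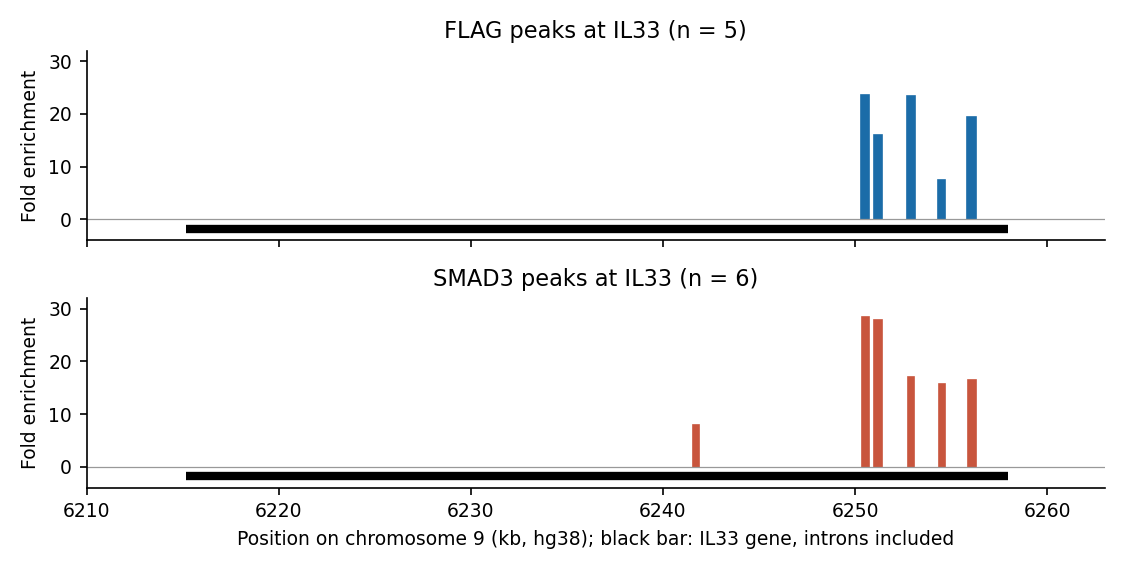
Peaks at IL33 on chromosome 9 (x axis, position in kb, hg38) in the FLAG list (top, 5 peaks) and the SMAD3 list (bottom, 6 peaks). Each bar spans a peak and its height is the authors' fold enrichment (y axis). 5 peaks lie at matching positions in both lists, and the black bar marks the gene.

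Of 18 genes of the ATOH8, SMAD3, TGF-beta and cell cycle programmes examined with their flanks of 10 kb, 12 had no peak in either list: SMAD7, SKIL, ID2, ID3, CDKN1A, CDKN2B, CCND1, CCNE1, CCNB1, MYC, E2F1 and JUNB. In the same window only 16.4% of all protein-coding genes had a FLAG peak and 16.1% a SMAD3 peak. Most genes therefore lacked both, and the 12 do not set these programmes apart. FLAG peaks with a q under 0.05 lay at 2 of the 18. CDH1, which encodes E-cadherin, carried 2 such peaks inside the gene, at 10.2-fold (chromosome 16, 68739549 to 68740553) and 3.81-fold. The other was ATOH8 itself, with the peak described above and a peak of 3.84-fold 9708 bp outside the gene. No SMAD3 peak at these 18 genes had a q under 0.05. Such peaks, in or within 10 kb of a gene, were rare throughout. In the lists without peaks far from genes, with high input background or at IL33, ALKBH5 and ATOH8, 117 protein-coding genes (0.584%) carried one. The FLAG share was 2.71%. Of SMAD3 peaks with a q under 0.05, 55.6% lay over 250 kb from any gene. Their absence at 18 genes therefore says little about SMAD3 there. SMAD3 itself had 3 SMAD3 peaks of 2.51- to 3.14-fold and no FLAG peak, CDK1 had a SMAD3 peak of 3.09-fold with 6 tags, and CDKN1B, a cell cycle inhibitor, had a FLAG peak of 2.35-fold with 5 tags and a SMAD3 peak of 2.93-fold with 6 tags. ID1, a BMP target, had a FLAG peak of 3.16-fold 9414 bp outside the gene.

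Cell cycle genes carried no more gene-end peaks than other genes of their length. Among 123 genes of the G1/S, G2/M and cyclin, CDK and E2F lists, CCND3 (3.56-fold) and NCAPD2 (3.64-fold) had a FLAG peak, against 2.28 expected, and CDC25C (3.56-fold) and PCNA (3.14-fold) had a SMAD3 peak, against 1.91 expected. The ratios were 0.878 and 1.05, and 6699 and 5745 of 10000 random lists had as many. All 4 peaks had 8 or 9 tags and a q above 0.05, and those near CCND3 and CDC25C lay inside TAF8 and FAM53C. With such low counts only a large excess could have been seen.

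With gene-end peaks, 0 of 20 gene lists passed the correction in the FLAG list (lowest adjusted value 0.62) and 0 in the SMAD3 list (lowest 0.42). None passed with wider windows either. The lowest values there were 0.058 for ribosomal protein genes with FLAG peaks within 5 kb of a gene end (9 of 73 against 3.0 expected, 29 of 10000 random lists as many) and 0.138 for cyclins, CDKs and E2Fs with SMAD3 peaks in or within 10 kb of the gene (10 of 32 against 4.41, 69 of 10000). Counts of gene-end peaks follow. G1/S genes had 0 of 43 members with a FLAG peak and 1 with a SMAD3 peak, G2/M genes 1 and 1 of 54, and cyclins, CDKs and E2Fs 1 and 1 of 32. Cell cycle inhibitors had 1 (CDKN1B) and 0 of 41. TGF-beta target genes (45), epithelial genes (36), fibroblast and endothelial genes (20) and replication-dependent histone genes (52) had 0 in both lists. BMP target genes had 2 and 2 of 28: ATOH8 and BMPER (2.83-fold) in the FLAG list, ATOH8 and HEY1 (3.83-fold) in the SMAD3 list. The ATOH8 peaks counted here and among bHLH factors are those described above, on implied input backgrounds of 321 and 297 tags. TGF-beta and BMP pathway components had 0 and 1 (TGFB2, 3.19-fold) of 40, and bHLH factors 1 (ATOH8) and 3 (ATOH8, HEY1 and TCF4) of 56. Mesenchymal genes had 0 and 1 (SPARC, 3.68-fold) of 40. Hypoxia genes had 2 (PLOD2, 3.95-fold, and SLC2A3) and 0 of 40, p53 targets 1 (PPM1D) and 0 of 36, and AP-1 and immediate early genes 2 (MCL1 and JUND) and 1 (IER5) of 35. NRF2 targets had 0 of 35 in the SMAD3 list. Lung epithelial lineage genes had 1 (SOX9, 4.11-fold) and 0 of 34, neuronal genes 1 (SNAP25) and 0 of 32, blood cell genes 0 and 2 (HBA2 and GNLY) of 32, and ribosomal protein genes 3 and 3 of 73.

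Shared peaks had more tags than unshared peaks but a slightly lower fold. The median fold of shared over unshared peaks was 0.936 in the FLAG list (2.96 against 3.16, 241 and 9225 peaks, two-sided permutation p = 2e-05) and 0.940 in the SMAD3 list (2.90 against 3.09, 243 and 6941 peaks, permutation p = 0.0012). The lower fold was not seen without peaks far from genes, with high input background or at IL33, ALKBH5 and ATOH8, a setting chosen after seeing the data. There the ratio was 1.00 in each list. Median pileups were 25 against 8 tags and 17 against 7 tags (permutation p = 1e-05 in each list, the smallest that 100000 permutations can give). The implied input background of shared peaks was 6.56 tags in the FLAG list, against 1.65 for unshared peaks, and 4.90 against 1.45 in the SMAD3 list. At gene ends only 4 peaks per list were shared, with a ratio of 1.27 in the FLAG list (permutation p = 0.01127) and 1.1 in the SMAD3 list (permutation p = 0.34791).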

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

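Comparisons with randomly placed or moved peaks used assigned chromosomes only, so peaks elsewhere are given here as signal those comparisons left out. Counts given with contigs included, and the comparison of shared with unshared peaks, did use them. The FLAG list held 365 peaks on contigs and alternate sequences, the strongest at 18.6-fold on KI270789.1 (104447 to 108144). The SMAD3 list held 203, the strongest at 5.85-fold on KI270715.1 (156940 to 157219). Mitochondrial peaks numbered 1 in the FLAG list and 2 in the SMAD3 list.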

How the results depend on the processing

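The settings that use a q under 0.05, moved peaks, lists matched on chromosome, or lists without peaks far from genes, with high input background or at IL33, ALKBH5 and ATOH8 (reduced lists) were chosen after seeing the data. The excess of overlap over chance held under all alternatives run, from 2.28 times chance upwards with 0 of 1000 placements as large. In the reduced lists, moved or placed peaks could land in the regions left out, so those ratios may be too high. The pooled 123 cell cycle genes carried no clear excess of peaks under any, at 0 to 1.14 times random lists. Their parts were not tested against each other. In the SMAD3 list within 10 kb of gene bodies, cyclins, CDKs and E2Fs had 10 of 32 against 4.41 expected (69 of 10000 lists as many, adjusted value 0.138). G1/S genes had 3 of 43 against 7.17 (481 of 10000 as few, not adjusted). Numbers of peaks fell to 681 FLAG and 85 SMAD3 at a −log10 q of 5 or more, 378 and 77 at a fold of 5 or more, and 2434 and 567 at a q under 0.05. The share of overlapping peaks was 1.76% (FLAG) and 2.29% (SMAD3) with 50% reciprocal overlap, 3.60% and 4.43% with gaps of up to 1 kb, 4.58% and 37.0% at a −log10 q of 5 or more, 3.49% and 15% at a q under 0.05, 2.03% and 1.95% among the 1000 strongest peaks, 1.96% and 2.56% without the 1% with the highest pileup, and 0.394% and 0.446% in the reduced lists. The gene-end share was 7.25% and 9.10% within 3 kb, 2.25% and 2.09% within 500 bp, 7.43% and 9.0% with all annotated genes, 1.69% and 1.37% at a −log10 q of 5 or more, and 2.21% and 2.09% at a q under 0.05. Against chance it reversed for FLAG at a −log10 q of 5 or more (0.543), and was no longer above chance for SMAD3 there (0.400, 1 peak), at a q under 0.05 (0.792 and 0.722) or, for FLAG, within 3 kb (1.02); the cause was not tested. Shared peaks, lower in fold, were higher by other measures: pileup ratios were 3.12 and 2.43, and −log10 q differed by 3.15 and 0.900 between medians. At gene ends, with 4 shared peaks each, fold ratios were 1.27 and 1.1, and in the reduced lists 1.00 and 1.00, where the difference was no longer past the threshold; the cause was not tested. The motif alternatives and the one that uses an annotation column of the authors were not run. Depth limits weak peaks most: 55.8% of FLAG and 78.4% of SMAD3 peaks rest on 8 tags or fewer.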

Other observations

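The tests in this part were chosen after the result was seen, except those of TGF-beta targets, cell cycle genes and the distance between FLAG and SMAD3 peaks, which were fixed before their results were seen but after other results. Gene names here were chosen after their values were seen. Among the 1012 FLAG peaks with a q under 0.05 in the lists without peaks far from genes, with high input background or at IL33, ALKBH5 and ATOH8, several lay in or within 10 kb of NRF2 targets and epithelial genes. ABCC2, an organic anion exporter, had a peak of 8.31-fold 6417 bp outside the gene (chromosome 10, 99775457 to 99776413), UGDH a peak of 6.62-fold, BACH1, a repressor of NRF2 targets, a peak of 4.74-fold, and TXNRD1, a thioredoxin reductase, peaks of 4.32- and 3.86-fold. In all, 4 of 35 NRF2 targets carried such a peak, against 0.775 expected, and 50 of 10000 random lists had as many (adjusted value 0.1 over 20 lists). Epithelial genes had 4 of 36 (CDH1, ELF3, and KRT8 and KRT18, which share 1 peak of 5.47-fold), against 1.05 expected, with 199 of 10000 random lists as high (adjusted value 0.199). Neither passed the correction. Wide FLAG peaks of at least 10-fold also lay in TGFBR3, a TGF-beta co-receptor (13-fold, chromosome 1, 91838950 to 91841716), KCNMA1 (13-fold), SAMD4A (14.5-fold) and THSD4 (27.8-fold). TGF-beta and BMP pathway components showed no excess of FLAG peaks of q under 0.05: TGFBR3 was the only 1 of 40, against 1.58 expected, and 8100 of 10000 random lists had as many.

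For TGF-beta target genes, 7875 of 10000 random lists had as many members with such a FLAG peak of q under 0.05. Of 123 cell cycle genes 1 (DLGAP5) did, and 9348 of 10000 lists had as many. Neither list therefore carried more such peaks than other genes of their length. The same FLAG peaks did lie near SMAD3 peaks: 78 of 1012 had a SMAD3 summit within 10 kb, against 56.4 ± 7.11 (SD, n = 1000 moved lists), and 3 of 1000 moved lists had as many. For the 5839 other FLAG peaks of those lists the ratio was 1.11, against 1.38, and 16 of 1000 moved lists had as many, so they too lay near SMAD3 peaks more often than moved peaks. The difference between both ratios was not tested. The excess may reflect common sites, but 1 library per antibody cannot separate that from regions that gather reads in any ChIP.

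Strong peaks at IL33 and ALKBH5 stood in both lists. Extra genomic copies of these regions would raise the input. The median implied input background of the FLAG peaks in the 6 strongest shared pairs was only 1.75 times that of the list. That argues against extra copies for the 6 as a set, but the values ran from 1.79 to 9.07 tags. The highest was at the IL33 pair starting at 6255822, with 9.07 tags in the FLAG list and 10.8 in the SMAD3 list. List medians were 1.65 and 1.47 tags, and the cause of the raised input there was not tested. Short DNA copies carried in both ChIP libraries, for instance as plasmid or cDNA, would give narrow peaks with matching summits. Of the 13 FLAG peaks of at least 15-fold elsewhere, 0 were as narrow as the widest IL33 peak of that fold (487 bp). Carried DNA is thus a candidate explanation for IL33, but width cannot decide it, since binding at a narrow site could give such widths too. The IL33 peaks were narrow only beside other strong FLAG peaks, as the median FLAG peak was 276 bp wide. For ALKBH5 carried DNA stays open, since 1 of the 13 and 13 of 37 others of at least 10-fold were as narrow as its strongest peak (925 bp). Summits of its strongest pair lay 81 bp apart, against a median of 43 bp for other shared pairs, and those of its weaker pair 31 bp apart. Binding of both proteins stays open at both genes, since summits 2 to 16 bp apart at IL33 (median 6 bp) would follow from either, and exon positions were not used here.

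Most shared peaks lay far from genes. Repeat arrays that gather reads from many copies are a likely source, since the median implied input background of shared FLAG peaks was 3.98 times that of unshared ones. Binding of both proteins at common sites near genes does not apply, by definition, to the 157 shared peaks over 250 kb from any gene. Binding far from genes was not tested. Binding near genes stays open for the 27 that were left, at 2.31 times moved lists, a ratio that may be too high, but most were weak. Only 1 of these pairs had a q under 0.05 in both lists, and it lay 174363 bp from any annotated gene (chromosome 2). Others were also distant within the 250 kb limit, such as 1 on chromosome 13 at 228179 bp from any gene. Some of these 27, such as 1 inside GTF2IRD2 and 1 that lies 54.8 kb from FRG2, still lie in or near gene families with close copies.

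Peaks per Mb differed between chromosomes in the same way in both lists, with a Spearman coefficient of 0.919 between the lists. The share of peaks at the genome-wide background floor fell as density rose, with a Spearman coefficient of −0.910 in the SMAD3 list and −0.809 in the FLAG list. Chromosomes with more reads in the input, as extra copies in this cell line could give, are thus a candidate explanation. No biological explanation was tested, because every library comes from the same cells.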
